A study of Mus musculus with 18 samples.

How the data were processed

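DNA methylation was measured by reduced representation bisulfite sequencing in 18 samples, 3 of each treatment in gonadal adipose tissue, hypothalamus and liver of male C57BL/6 mice at 3 weeks of age. Per the labels' protocols, 100 ng of DNA per sample was cut with MspI, ligated to adapters, size-selected, treated with bisulfite, amplified by PCR and sequenced. Reads were aligned with BSMAP to the build GRCm38 (mm10), per the submitters' processing notes, and its version is not given in the sources used here. Whether PCR copies were removed is not given either.

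The authors deposited 1 table per tissue, and each table sets a pool numbered 0 against a pool numbered 1. A label of the samples names the table with the control group before the BPA group, and number 0 was read as control on that basis alone. Each pool joins the 3 samples of its group, and no value per sample was used here. Per the file headers, the deposited read counts give the reads covering each CpG, with both strands together in rows of 2 bp. The deposited methylation fraction is the share of those reads that were methylated, rounded to 3 significant digits. The deposited p-value used here is that of Fisher's exact test between the pools, and recomputing it from counts and fractions gave the same value within rounding on 100% of 5000 sites per table. The other deposited columns, a nominal and a credible difference between the pools, are the authors' own comparison, of which the credible difference served only as an alternative setting. Every site listed had at least 3 reads in each pool. Positions are 1-based on GRCm38.

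The design fixed before the data were examined foresaw values per sample. Its logistic test per site with moderated spread, its permutation test of mean levels and its promoter and camera tests need such values or gene strands, and were not run. The planned use for deposited comparisons was followed instead. As no adjusted value is among the columns used, the deposited Fisher p was adjusted here by the Benjamini-Hochberg procedure over all nuclear sites with at least 10 reads in each pool. A site was called at an adjusted p under 0.05 with a difference of at least 5 percentage points, BPA minus control. This is a two-sided test of pooled reads. PCR reads without molecular identifiers are not independent molecules, CpG sites on 1 read are not independent, and no test here measures the spread between animals. Levels have exact Clopper-Pearson intervals and differences Newcombe intervals, both 95% and for counting error only. Mitochondrial sites were kept out of the tests.

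Gene positions came from a RefSeq table of the same assembly with 49980 genes used. It gives start and end but no strand, exon or intron, so a site was assigned to each gene whose body holds it, or otherwise to genes within 5 kb of either end. The 18 gene lists, with 447 entries that all matched, cover imprinted genes, nuclear and steroid receptors, adipogenesis, cholesterol and bile acid metabolism, fatty acid oxidation, insulin and glucose metabolism, feeding neuropeptides, clock genes, DNA methylation machinery and extracellular matrix. They also hold markers of leukocytes, endothelium, hepatocytes, adipocytes, neurons, oligodendrocytes, astrocytes, and epididymis and testis. The number of protein-coding list genes with a called site was set against 10000 random lists matched on the number of tested sites. A percentile places a list in the middle of the random lists that tie with it. Adjusted over the list alone, called sites in adipose rose in some lists and fell in others. They numbered 34 in the matrix list and 42 in the receptor list, against 28 and 32 adjusted over all sites, and 16 against 10 for cholesterol and bile acids. The hepatocyte, endothelial, oligodendrocyte and astrocyte lists had 12, 18, 23 and 12 against 4, 13, 12 and 6. Fewer were called for clock genes (0 against 5), fatty acid oxidation (1 against 9), methylation machinery (1 against 9), insulin and glucose (11 against 19), neuropeptides (5 against 6), adipogenesis (25 against 26) and neuron markers (6 against 8).

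The genes named in the text follow a rule fixed before the data were examined. Per tissue and direction, the 10 genes with the most called sites were named, ties by the smallest p, plus up to 2 further genes per list. Its condition on single animals fell away, as the rule foresaw for deposited comparisons. Genes outside the rule (Fgb, Cidec and Elavl3 for levels of control pools, and Scp2, Wbscr25, Aatk, Fads3, Cyp2j5, Matn4 and Pde1c) were chosen after their values were seen. Some genes, including ones within the rule, are not reported here.

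Tissues were compared by Fisher's exact test between control pools. Whether the difference between pools differed between tissues was tested by a Wald test of the difference of log odds ratios. Each cell of pooled reads had 0.5 added. Shares of called sites in gene bodies were compared with tested sites by Fisher's exact test. The excess over counting error is the mean over sites at 20 to 80% with at least 30 reads of the squared pool difference divided by its counting variance. The scripts were tested on simulated reads with the depths of each table, except that the deepest sites were cut to a fixed limit. Sites above that limit, which include called ribosomal RNA-like sites, were thus not simulated at their depth. Known changes were placed only at sites of middle level, with the least covered sites left out. Of sites changed by 20 and 30 points, 41% and 76% were called in adipose, 20% and 55% in hypothalamus and 35% and 77% in liver. With counting error only, 1, 1 and 3 unchanged sites were called among 1876099, 1569349 and 1628817. With animals varying by an SD of 3 points at a level of 50%, 52, 8 and 17 unchanged sites were called. With an SD of 5 points at that level, 5041, 1071 and 3279 were called.

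Alternatives varied the read minimum, the minimum difference, the adjusted p, the range of levels, the deepest sites, 500 bp windows, ribosomal RNA-like genes, the credible difference and the scaling of p-values. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.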

Results

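The series asks how exposure to bisphenol A (BPA) before birth relates to DNA methylation in 3 tissues of mouse offspring. BPA is a plasticizer monomer with weak oestrogen-like activity. Pregnant C57BL/6 dams received BPA in corn oil at 5 mg per kg per day, or corn oil alone, by gavage from day 1 to day 20 after conception. Gonadal adipose tissue, hypothalamus and liver were taken from male offspring at 3 weeks of age, with 3 samples for each treatment and tissue, 18 in all. The offspring came from 3 control litters and 4 BPA litters, and the litter of each sample is not given in the sources used here. Reduced representation bisulfite sequencing (RRBS) was used, in which DNA is cut at CCGG by MspI and unmethylated cytosines are converted, so that methylation is read at single CpG sites in CpG-rich fragments.

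The deposited values join the 3 samples of a treatment and tissue into 1 pool, so every level below is the authors' pooled value with no error between animals. Pools are numbered 0 and 1 in the tables. Number 0 was read as control and 1 as BPA, after the order of the groups in a label, and no label states the numbering. If it were the reverse, every direction between the pools below would turn, the counts and shares of higher and lower sites would change places, and the total of called sites would stay. The adipose table listed 1946477 CpG sites, with coverage that summed to 359584229 reads in the control pool and 409016549 in the pool read as BPA. For hypothalamus 1687641 sites were listed with 213672622 and 226986996 reads, and for liver 1705876 sites with 316707522 and 286763812. Wherever reads are summed over sites, here and below, a read is counted once at each CpG that it covers. The median number of reads per site was 144 and 164 in adipose, 93 and 98 in hypothalamus, and 136 and 127 in liver. Sites with at least 10 reads in each pool on nuclear chromosomes were tested, 1876099 in adipose, 1569349 in hypothalamus and 1628817 in liver. A site was called when its pools differed by at least 5 percentage points at a Benjamini-Hochberg adjusted Fisher p under 0.05. This test compares the pooled reads, not the animals or the treatments. All intervals are 95% intervals, and those of levels and differences are for counting error only. Those of shares of sites take sites as independent, and are too narrow where neighbouring sites share reads.

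The control pools differed between tissues at the genes that mark their cells. Over the CpG sites of the hepatocyte gene Fgb, which encodes fibrinogen beta, 23.7% of 2386 reads were methylated in liver, against 82.5% of 2766 reads in adipose and 91.3% of 1584 in hypothalamus. Of 15 hepatocyte marker genes, 11 had their lowest level in liver, where the median gene level was 64.2%, against 78.5% in adipose and 86.2% in hypothalamus. Of 12 adipocyte marker genes, 7 were lowest in adipose, among them Plin1, which coats lipid droplets, at 62.3% against 77.2% in hypothalamus and 73.5% in liver. Another adipocyte marker, Cidec, was instead lowest in liver at 46.9%. Of 16 neuron marker genes, 9 were lowest in hypothalamus, such as Elavl3, an RNA-binding protein of neurons, at 14.8% against 20.2% in adipose and 20.6% in liver. Endothelial and leukocyte markers were lowest in adipose for 9 of 13 and 9 of 16 genes, astrocyte markers in hypothalamus for 5 of 9, and oligodendrocyte markers in hypothalamus for 6 of 11. Markers of epididymis and testis, tissues next to gonadal fat, were lowest in adipose for 4 of 11 genes.

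Site by site, Fisher's exact test on the control pools called 204196 sites between adipose and hypothalamus, 144089 of them higher in hypothalamus. It called 270043 sites between adipose and liver, 138036 of them higher in liver, and 258795 between hypothalamus and liver, of which 171151 were lower in liver. These counts are 12.9%, 16.5% and 16.9% of the sites with at least 10 reads in both control pools.

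In gonadal adipose tissue, Hlx, a homeobox gene on chromosome 1 (184727143 to 184732493), had 10 called sites within 367 bp, from 184727524 to 184727890, all higher in the pool read as BPA by a median of 64.6 percentage points. Its leading site at 184727877 went from 2.5% of 40 reads to 75% of 16 reads, a difference of 72.5 points with an interval of 45.9 to 87.5. With at least 20 reads in each pool only 1 Hlx site was called. Zfhx3, another homeobox gene (chromosome 8, 108279311 to 108961636), had 10 higher and 1 lower site spread over its body, led by one at 66.9% of 335 reads in the control pool and 88.3% of 317 reads in the BPA pool. Irx1 and Shh, a homeobox gene and a secreted morphogen of development, had 9 lower sites each, and Shh had 1 higher site.

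Hoxd3 had 8 higher sites (median 30.3 points), led by 13.4% against 36.7% at 74740634 on chromosome 2. Actn1, the cytoskeletal cross-linker alpha-actinin 1, had 9 higher sites with a median of 13.3 points. Camta1 had 8, Nav2 had 7 and Ldlrad3 had 6 higher sites, with medians of 16.6, 14.1 and 12.1 points, and Camta1 and Ldlrad3 also had 4 and 2 lower sites. A set of 3 overlapping gene models on chromosome 18, Gm37013, Gm38666 and Gm38667, span the protocadherin gene cluster and share most sites. Gm37013 (36952648 to 37841873) held 7 higher and 9 lower sites, and the other models held 6 higher and the same number of lower sites each.

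Among genes with lower methylation in the pool read as BPA, the leading site of Irx1 at 71957622 on chromosome 13 went from 28.1% of 196 reads to 5.43% of 221 reads. At Shh the leading site at 28459873 on chromosome 5 went from 19.2% to 5.31%. The Y chromosome models LOC108168645 and Mid1-ps1 had 13 and 10 lower sites. The ribosomal RNA-like models AY036118 and Rn18s-rs5 on chromosome 17 had 32 and 25 lower sites, led by a shared site at 39845148 with 24.9% of 42213 reads and 19.4% of 48357 reads.

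Of the 18 gene lists, 17 had at least 1 called site in adipose. Extracellular matrix and adhesion genes had called sites in 16 of 31 genes, above the 10.0 expected for random lists with as many tested sites (95% range 6 to 15, percentile 99.3). Col4a1, a basement membrane collagen, had 5 higher sites, led by 46.6% against 62.5% at 11308904 on chromosome 8, and Timp2, a metalloproteinase inhibitor, had 2 higher sites. Over the whole list 16 sites were higher and 12 lower, with higher sites in 9 genes and lower sites in 10. Nuclear and steroid receptors had called sites in 19 of 36 genes, against 14.1 expected (percentile 97.2), with 13 sites higher and 19 lower. Thra, the thyroid hormone receptor alpha, had 2 higher sites, led by 37.3% against 60.3%. Esrra, the oestrogen-related receptor alpha, had 3 lower and 2 higher sites. The matrix list and the hepatocyte markers, 2 of the 18 lists, stood in the top 2.5% of their random lists, where chance would place 0.45. The random lists describe these pools and give no test across animals. They were not matched on methylation level, and sites at 20 to 80% made up 50.8% of called and 21.9% of tested adipose sites. They therefore cannot tell whether a list holds more called sites than others at equal level.

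The remaining pathway lists lay inside the range of their random lists in adipose. Adipogenesis genes had called sites in 9 of 36 genes, among them Prdm16, a regulator of brown fat, with 4 higher and 5 lower sites, and Zfp423, a preadipocyte regulator, with 2 lower and 1 higher. Insulin and glucose genes had them in 13 of 35, with Igf1 lower (86.6% against 68.7%) and Igf1r higher (27.2% against 44.2%) at their leading sites. Cholesterol and bile acid genes had them in 8 of 34, where Fdft1, squalene synthase, was lower (39.9% against 23.7%) and Abcg1, a cholesterol exporter, higher (76.8% against 88.2%). Fatty acid oxidation genes had them in 6 of 25, with Ucp2 lower (92.1% against 77.7%) and Acaa1a higher (80.8% against 90.5%). Of 43 protein-coding imprinted genes 14 had called sites. Over the whole imprinted list 6 sites were higher and 16 lower, with Igf2r and Usp29 lower at 2 sites each. Neuropeptide and feeding genes had them in 4 of 34, including Pcsk2 (71.3% against 50.4% at its leading site) and Ghrh (14.6% against 41.1%). Clock genes had them in 4 of 21, with 2 sites higher and 3 lower, the lower ones including Hlf and Dbp, and methylation machinery genes in 7 of 29, with Uhrf1 higher (54.2% against 86.7%) and Tet3 higher at 1 site and lower at another (94.8% against 79.9%). With p-values adjusted over each list alone, the clock list had 0 called sites instead of 5, the fatty acid oxidation and methylation machinery lists 1 each instead of 9, and the insulin and glucose list 11 instead of 19.

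Marker genes of other cell types also carried called sites in adipose. Pecam1, an adhesion molecule of endothelial cells, had 5 lower sites between 106715262 and 106715708 on chromosome 11, led by 67.9% of 271 reads against 43.4% of 297 reads. With at least 20 reads in each pool, 2 Pecam1 sites were called. Called sites stood in 5 of 13 endothelial genes, 3 of 17 leukocyte genes, 4 of 15 hepatocyte genes (percentile 97.7), 3 of 12 adipocyte genes and 4 of 15 protein-coding neuron genes. They stood in 5 of 12 oligodendrocyte genes, 4 of 9 astrocyte genes and 0 of 13 epididymis and testis genes. Endothelial genes had 3 higher and 10 lower sites, leukocyte genes 0 and 3, hepatocyte genes 3 and 1, and adipocyte genes 2 and 1. Neuron genes had 6 and 2, oligodendrocyte genes 3 and 9, and astrocyte genes 4 and 2. Counted by genes with lower sites, the endothelial and leukocyte lists stood at percentiles 97.2 and 96.1. By genes with higher sites, the hepatocyte list stood at 98.4. Flt1 was higher at 1 site and lower at 2, Mbp was lower at 4 sites, and Cspg4 was lower at 3 sites and higher at 1. Gja1 was higher at 3 sites, Serpina1a, F2, Plin1 and Camk2a were higher at 1 site each, and Cd52, Slc7a10 and Aldh1l1 were lower at 1 site each. Gad1 had 1 higher and 1 lower site.

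In all, 10029 adipose sites were called, 4724 higher and 5305 lower in the pool read as BPA, with a median absolute difference of 15.4 points. Sites with 20 to 80% methylation made up 50.8% of them and 21.9% of the tested sites. Called sites lay in gene bodies in 63.6% of cases (interval 62.7 to 64.5) against 65.9% of tested sites (Fisher's exact test, adjusted p = 1.50e-06), and 25.4% lay over 5 kb from any gene against 22.0%. The mean level over tested sites was 50.3% in the control pool and 50.1% in the BPA pool, a difference of -0.151 points. The squared difference between the adipose pools was on average 2.22 times that of counting error. With p-values scaled by this excess, 18 adipose sites were called (5 higher, 13 lower), of which 12 belonged to AY036118, with 5 of these shared by Rn18s-rs5, and 1 to Wbscr25, and the other 5 lay over 5 kb from any gene.

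**Figure D1:**
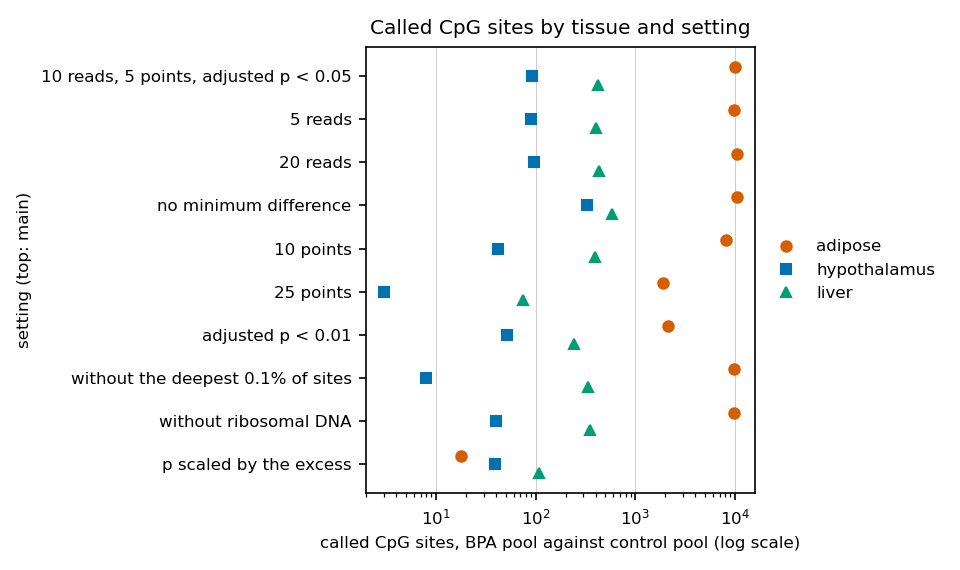
Number of called CpG sites between the control pool and the pool read as BPA (horizontal log axis) in adipose (circles), hypothalamus (squares) and liver (triangles) under the settings named on the vertical axis. Adipose led with 10029 sites in the main setting and had the fewest, 18, when p-values were scaled by the excess over counting error, against 39 in hypothalamus and 108 in liver.

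**Figure D2:**
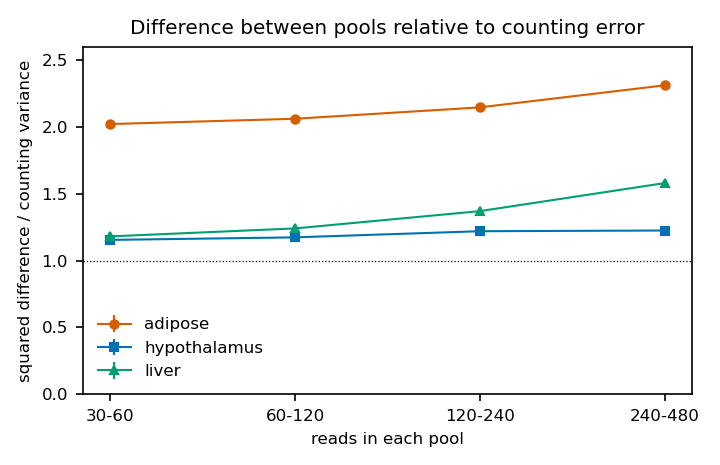
Mean squared difference between the pools divided by its counting variance (vertical) for sites at 20 to 80% methylation, by reads in each pool (horizontal), in adipose (circles), hypothalamus (squares) and liver (triangles), with bars of 1 standard error over sites; the dotted line at 1 is counting error alone. Adipose lay at 2.02 to 2.31 at all depths, and liver went from 1.18 to 1.58.

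**Figure D3:**
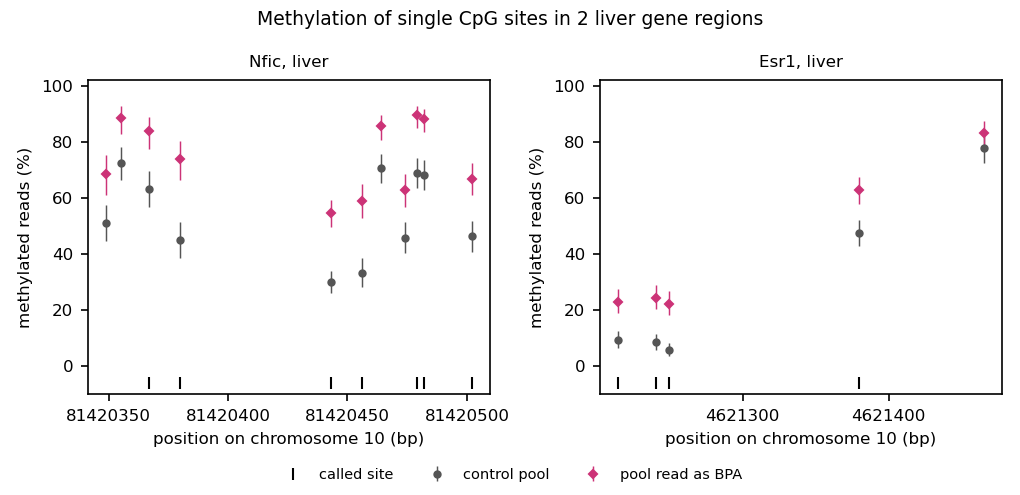
Percent of methylated reads (vertical) by position in bp (horizontal) at CpG sites of Nfic and Esr1 in liver, for the control pool (circles) and the pool read as BPA (diamonds). Bars are exact 95% intervals for counting error and ticks mark called sites; levels were higher in the BPA pool at the 7 called Nfic and 4 called Esr1 sites.

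In the hypothalamus, the protein-coding gene with the most called sites was Tmem267, a transmembrane protein gene. It had 14 sites with lower methylation in the pool read as BPA, from 119488088 to 119489045 on chromosome 13, in a gene annotated from 119488086 to 119610459. Its leading site at 119488873 went from 66.9% of 514 reads to 47.9% of 380 reads, a difference of -19 points with an interval of -25.4 to -12.5. The neighbouring long noncoding RNA gene 3110070M22Rik had 9 lower sites, led by 25.5% of 161 reads against 5.8% of 207 reads. Some of these sites lie in both genes.

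Deeply covered models held most of the higher sites in the hypothalamus. AY036118 had 18 higher sites with a median of 5.65 points and Rn18s-rs5 had 15 higher and 1 lower, sharing sites with it. The leading site of AY036118 at 39848243 went from 39.7% of 10407 reads to 48.2% of 10861 reads. Gm19064 and LOC115490388 on chromosome 6 shared 6 higher sites between 3201523 and 3201577. A site at 101425987 on chromosome X, within 5 kb of both Nono and Zmym3, went from 24.7% of 283 reads to 46.8% of 222 reads.

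Most other named hypothalamic genes had 1 site each. Cdh20, a cadherin, was higher (41.8% against 57.8%), as were A330008L17Rik, Gm34922 and Cdc20, an activator of the anaphase-promoting complex (2.76% against 12.3%). D5Ertd579e was lower (84.4% against 64.6%), as were Mctp1 (98.1% against 77.2%), the signalling adaptor Traf3 (90.7% against 73.2%), 9630028I04Rik, Gm46046 and Gm33272. Mid1-ps1 was lower at 3 sites. None of the genes in the 18 lists had a called site in the hypothalamus, the feeding neuropeptide and neuron lists included. With so few calls, random lists averaged only 0.0189 and 0.0117 genes with a called site for these lists. The absence therefore says nothing about these genes.

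Over all hypothalamic sites 92 were called, 45 higher and 47 lower in the pool read as BPA, and 53437 sites, 3.41%, had an unadjusted p under 0.05. The smaller pool held a median of 1190.5 reads at called sites, and gene bodies held 39.1% of them (interval 29.1 to 49.9) against 66.2% of tested sites (Fisher's exact test, adjusted p = 5.63e-07). Mean levels were 50.5% and 50.6%, a difference of 0.0695 points. Without the deepest 0.1% of sites 8 calls were left, 4 higher and 4 lower, 2 of them at Tmem267 and none at AY036118 or Gm19064. With p-values scaled by the excess of 1.26, 39 calls were left, 27 of them higher, and 281 of 328 sites were higher when no minimum difference was asked.

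Nearly unmethylated sites moved with the groups in the hypothalamus as well. Over 168239 nuclear sites under 1% in the pools of the other tissues, 0.459% of reads were methylated in the control pool and 0.868% in the pool read as BPA. Over the corresponding sites the level was 0.459% and 0.460% in adipose and 0.755% and 0.578% in liver.

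**Figure D4:**
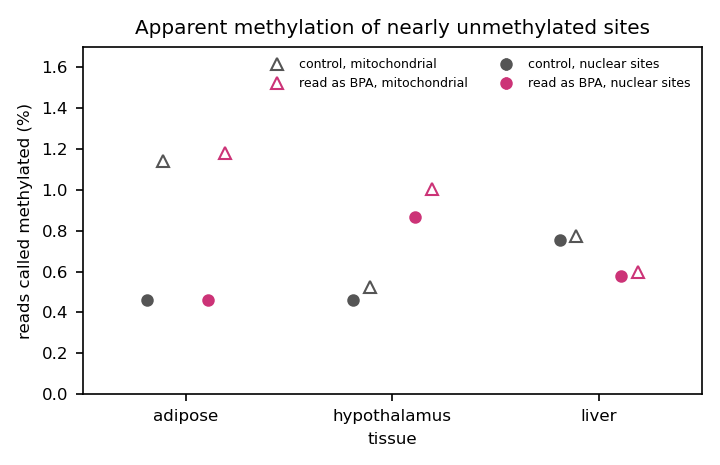
Percent of reads called methylated (vertical) in each tissue (horizontal) for the control pool (grey) and the pool read as BPA (pink), over nuclear sites under 1% in the other tissues (circles, exact 95% intervals within the symbols) and over 13 mitochondrial CpG sites (triangles). In hypothalamus both kinds of site were higher in the BPA pool, the nuclear sites by 0.409 points and the mitochondrial sites by 0.482 points.

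**Figure D5:**
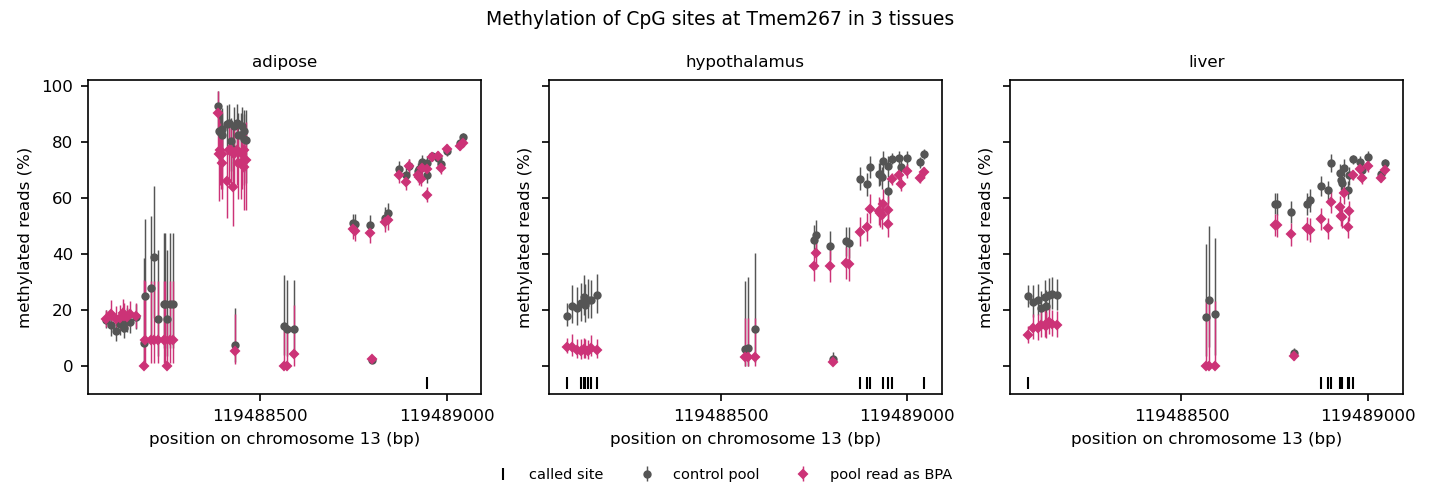
Percent of methylated reads (vertical) by position on chromosome 13 in bp (horizontal) at CpG sites of Tmem267 in adipose, hypothalamus and liver, for the control pool (circles) and the pool read as BPA (diamonds), with exact 95% intervals for counting error and ticks at called sites. Over 18 sites called in hypothalamus or liver the mean difference was -14.7 points in hypothalamus, -10.4 in liver and -0.7 in adipose.

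In the liver, Esr1, the oestrogen receptor alpha (chromosome 10, 4611989 to 5005633), had 4 sites of higher methylation in the pool read as BPA, from 4621215 to 4621381. Its leading site at 4621250 went from 5.69% of 404 reads to 22.3% of 391 reads, a difference of 16.6 points with an interval of 11.9 to 21.3. Nfic, a transcription factor of the nuclear factor I family, had 7 higher sites within 137 bp (81420367 to 81420503 on chromosome 10), led by 29.9% of 515 reads against 54.5% of 409 reads, a difference of 24.6 points (interval 18.3 to 30.7).

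Slc2a5, a fructose transporter, had 5 higher sites, led by 46.2% of 702 reads against 65.1% of 621 reads at 150128564 on chromosome 4. Acot11, a fatty acyl-CoA thioesterase, had 4 higher sites, led by 38.8% against 62.9% at 106767625 on the same chromosome. Camkk2, a kinase upstream of AMP-activated protein kinase, had 4, led by 24.6% against 49.5%. Klhdc7a had 8 higher sites with a median of 19.5 points, Hhipl1 had 7 (20.3 points), Col27a1 had 6 (19.4 points), and Dpf3 had 4 (27.5 points). The noncoding gene Gm31901 held a site at 95683172 on chromosome 16 that went from 33.3% of 468 reads to 69.1% of 392 reads, at an adjusted p of 5.54e-20.

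Lower methylation in the liver pool read as BPA was found at Tmem267 (10 sites, median -12.6 points) and 3110070M22Rik (7 sites, median -15.3 points), as in the hypothalamus. Lrrc8d, a subunit of volume-regulated anion channels, had 6 lower sites, led by 57.2% of 276 reads against 30.9% of 243 reads. Dlg2, a synaptic scaffold protein, had 6, Zmiz1 had 5, and Ido2, an enzyme of tryptophan breakdown, had 3, led by 43.4% against 25.2%. Hspa12b and Klhl29 had 2 each. Rn18s-rs5 and AY036118 had 15 and 14 lower sites, which they mostly share, led by 90.7% of 140 reads against 52.2% of 136 reads at 39846203 on chromosome 17, and 1 higher site.

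Of the 18 lists, 4 had a called site in the liver, and none stood in the top 2.5% of its random lists. Nuclear and steroid receptors had called sites in 3 of 36 genes, against 0.896 expected (percentile 96.7), among them Esr1 and Nr2f1, which was higher (24.7% against 58.1%). The insulin receptor Insr was higher at 1 site (50.9% against 64%), the methyltransferase Dnmt3a lower at 1 (21.6% against 10.9%), and the neuron marker Rbfox3 higher at 1 (36.6% against 51.7%). The imprinted, adipogenesis, cholesterol and bile acid, fatty acid oxidation, neuropeptide, clock and matrix lists had 0 called sites, as did the leukocyte, endothelial, hepatocyte, adipocyte, oligodendrocyte, astrocyte, and epididymis and testis markers.

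Over all liver sites 421 were called, 294 higher (69.8%, interval 65.2 to 74.2) and 127 lower (30.2%), shares that would change places if the pools were numbered the other way, with a median absolute difference of 18.3 points. The share of higher sites was 54.96% (144 of 262) with the deposited credible difference, a setting chosen after seeing the data, and 57.4% (1533 of 2672) in windows of 500 bp. Sites with 20 to 80% methylation made up 83.6% of them, against 21.7% of tested sites. Gene bodies held 67.0% of called and 65.5% of tested sites (Fisher's exact test, adjusted p = 0.77). The mean level over tested sites was 50.5% in both pools, a difference of -0.0471 points, which turned to 0.528 points when total methylated reads were divided by total reads. With p-values scaled by the excess of 1.39, 108 calls were left, 84 higher and 24 lower, with 8 at Klhdc7a, 5 at Nfic, 2 at Esr1 and 0 at Zmiz1, Hspa12b, Klhl29 and the genes named singly from the lists.

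Across tissues, called sites coincided at a few places. A block on chromosome 12 from 20231567 to 20233466, over 5 kb from any annotated gene, held 9 sites called in more than 1 tissue, higher in the pools read as BPA in all 3 tissues, by means of 9.28, 6.86 and 8.11 points in adipose, hypothalamus and liver. A block on chromosome X from 169998279 to 169998334 held 6 such sites, all lower. On chromosome Y, Mid1-ps1 held 3 and a block from 90772615 to 90772667 held 6, called as lower in adipose and hypothalamus. Sites of the X block and of this Y block stood at matching spacing and similar levels. Adipose was at 57.2% against 48.9% at 169998279 on X, and at 55.1% against 48.8% at 90772615 on Y. These blocks may thus be copies of 1 sequence and not separate places. The Tmem267 and 3110070M22Rik block held 9 shared sites, with means of -13.0 points in hypothalamus, -12.7 in liver and -2.09 in adipose. The shared sites of the chromosome 12 block had at least 580 reads in every pool, and those on X and Y at least 1000. The median over all listed sites was 93 to 164 reads by pool. Whether sequence with many copies gave this depth was not tested. A Slc2a5 site at 150128631 was higher in adipose (12.3 points) and liver (16.8 points). A site of Scp2, a sterol carrier protein, was called in opposite directions, -13.1 points in adipose and 24.4 in liver.

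In numbers, adipose and hypothalamus shared 18 called sites against 0.524 expected by chance, 17 in the same direction (Fisher's exact test, adjusted p = 2.31e-22). All of these lay in the blocks on chromosomes 12, X and Y or at the ribosomal RNA-like genes. If the X and Y blocks are copies of 1 sequence, its sites are counted more than once. Adipose and liver shared 25 against 2.45 expected, 23 in the same direction (exact test, adjusted p = 1.82e-17). Hypothalamus and liver shared 14 against 0.026, all 14 in the same direction (exact test, adjusted p = 6.03e-34). Nearby CpG sites share reads and are not independent, so these p-values are too small. The expected numbers also take all tested sites as equally likely to be called, while called sites were more often deep and of middle level. They are therefore too low. Without ribosomal RNA-like genes, a setting chosen after seeing the data, the shared sites fell to 11, 14 and 7 in the same order. The sites lost were not all ribosomal, as the adjusted p of other sites changes too. In hypothalamus calls fell from 92 to 40, while 21 of the 92 lay in or within 5 kb of those genes. Of the sites called in adipose and differing at all in liver, 51.2% had the same sign there (interval 50.2 to 52.2), and in hypothalamus 50.9% (interval 49.8 to 52.0). Of the sites called in hypothalamus 83.5% had the same sign in liver (interval 74.3 to 90.5) and 52.2% in adipose (interval 41.4 to 62.9). Of the sites called in liver, 54.5% had the same sign in hypothalamus (interval 49.6 to 59.4) and 55.3% in adipose (interval 50.4 to 60.2). These intervals take sites as independent and are too narrow. The 92 sites called in hypothalamus formed only 41 runs of neighbouring sites with the same direction.

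The difference between pools itself differed between tissues at some of these genes, by a Wald test of log odds ratios at an adjusted p under 0.05. In AY036118, a site at 39848621 was -4.2 points in adipose and 2.6 points in hypothalamus, pools read as BPA against control. Sites that passed this Wald test numbered 385 between adipose and hypothalamus, of which 99 were called in adipose. They numbered 627 between adipose and liver, of which 290 were called in adipose, and 14 between hypothalamus and liver. For the remaining sites called in adipose, the difference was not shown to be specific to that tissue. The Wald test takes pooled reads as its units, so the sites that passed describe these pools and not the animals.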

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

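The tests of bisulfite conversion, of depth at equal reads and of the adipose values at Tmem267 were chosen only after the results were seen. The tests of cell mixture, PCR copies and copy number were written before.

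Over 13 mitochondrial CpG sites, kept out of the comparisons, 1.01% of 273403 reads were methylated in the hypothalamus pool read as BPA (interval 0.968 to 1.04), against 0.524% of 236820 reads in the control pool. Adipose had 1.14% and 1.18%, and liver 0.776% and 0.597%. A candidate explanation is a difference in bisulfite conversion between the hypothalamus pools, which would raise all unmethylated sites alike. Over nuclear sites under 1% in the other tissues, the hypothalamus difference was 0.409 points, close to the mitochondrial 0.482, so this explanation stays open. A treatment difference in mitochondrial DNA was not tested apart from it.

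Adipose had 10029 called sites against 92 and 421. A difference in the share of liver-like or hypothalamus-like cells is argued against, since differences at called adipose sites did not follow the tissue contrast (Pearson r over sites -0.00872, sites not being independent). That contrast cannot speak of other cell types. A difference in the share of endothelial cells or leukocytes, whose marker directions are given above, stays open and was not tested. At sites thinned to 60 reads per pool no tissue had a call, a void test, and a thinning to 150 reads, chosen after that, gave 31 adipose and 33 liver calls, a ratio of 0.939 (interval 0.556 to 1.58) that leaves depth open for the count of calls. At these equal reads the share of sites with an unadjusted p under 0.05 was still 1.61 times that of liver (4.78% against 2.96%), which depth alone would not give. PCR copies counted as separate reads may account for much of the excess, as its mean at 240 to 480 reads was 1.14 times that at 30 to 60 reads. It still rose from 2.02 to 2.31, and a spread between animals and a treatment difference, which would both grow with depth, stay open and untested.

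The Tmem267 block was lower in the hypothalamus and liver pools read as BPA. Summed over the 18 sites, the ratio of covering reads departed from that of all sites by 1.101 times at most. This goes against a copy number difference over the block as a whole. Hypothalamus sites went both ways by stretch. Each tested site from 119488873 to 119488949 had fewer BPA reads, with 514 control and 380 BPA reads at the first. Each from 119488088 to 119488168 had more, with 161 and 207 at the last. The sum also leans on deep sites at 119488960 (1835 and 1934 reads) and 119489044 (2242 and 2539). The summed ratio cannot settle a copy number difference in parts of the block, which stays open. A difference carried by all tissues of the same animals would lower adipose as well, by over 5 points, and the adipose mean was -0.7 points (over summed reads -1.46, interval -2.40 to -0.520, too narrow where CpGs share reads). That argument rests on the tissues sharing animals, which the labels do not state. A treatment difference in these tissues, or different animals in the pools, may remain, and neither was tested.

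The difference between pools differed between tissues by a direct test at 385 sites between adipose and hypothalamus, 627 between adipose and liver, and 14 between hypothalamus and liver. The test takes pooled reads as its units and measures no spread between animals. It cannot show that a treatment difference differs between tissues. The strongest of the first kind lay in AY036118.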

How the results depend on the processing

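No paired analysis was possible because the deposited values join the replicates of each group. For the same reason the logistic, limma, edgeR and unmoderated fits, the replicate block, leaving out replicates and the random splits were not run. Promoter and camera rows were not run for lack of gene strands. Scaled p-values, the credible difference, the setting without ribosomal RNA-like genes and the minimum of 30 reads were chosen after seeing the data. Causes of the changes below were not tested.

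At 25 points, 1883 adipose, 3 hypothalamus and 75 liver sites were called, and at an adjusted p under 0.01, 2120, 52 and 242. Scaled p-values left 18, 39 and 108, and the deposited credible difference of at least 20 points gave 2479, 232 and 262. Levels of 5 to 95% gave 15623 in adipose. Windows of 500 bp gave 2366 in hypothalamus and 2672 in liver. Hypothalamus had 42 at 10 points, 328 with no minimum difference, 8 without the deepest 0.1% of sites and 40 without ribosomal RNA-like genes. Its share of higher sites turned from 48.9% to 85.7% with no minimum difference, 59.6% at an adjusted p under 0.01 and 69.2% with scaled p-values, and moved to 31.0% at 10 points and 0% at 25 points. In liver it moved from 69.8% to 54.96% with the credible difference and 57.4% in windows. With the pools numbered the other way, these would be shares of lower sites. With total methylated over total reads, the mean difference was -0.255 points in adipose, 0.143 in hypothalamus and 0.528 in liver, a reversal in liver, and with 5 reads it was 0.0816 in hypothalamus.

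At 25 points the control pools differed at 74108, 92397 and 93211 sites for adipose with hypothalamus, adipose with liver, and hypothalamus with liver. In the same order, sites called within 500 bp of each other numbered 61, 93 and 41, and shared sites without ribosomal RNA-like genes 11, 14 and 7. Minimums of 5, 20 and 30 reads kept called counts within 1.5 times. Of 99 named gene results, 97 stayed within 1.5 times with 20 reads (not Hlx, 1 site, and Pecam1, 2 sites), 82 at 10 points and 12 with scaled p-values, where 70 had no called site left. Depth limits the test, since 20-point changes were found in 20 to 41% of simulated sites of middle level.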

Other observations

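The test of homeobox genes below was chosen only after the result was seen, as were the places described here.

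Liver sites outside the naming rule gave further gene places that passed with scaled p-values, a setting chosen after seeing the data. In Aatk, a kinase gene on chromosome 11, 3 sites from 120010221 to 120010287 were higher in the pool read as BPA, the first of them 41.3% of 206 reads against 69.9% of 166 reads. Fads3, a fatty acid desaturase gene, was higher at 10046421 on chromosome 19 (11.7% against 32.9%), and Cyp2j5, a cytochrome P450 gene, at 96637726 on chromosome 4 (64.6% against 86.2%). Matn4 and Pde1c were lower, from 85.6% to 70.8% and from 94.8% to 83.9%. In adipose, 1 site of Wbscr25 passed as well, at 134998636 on chromosome 5, with 30.4% of 369 reads against 54.5% of 527 reads.

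The ribosomal RNA-like sequence on chromosome 17 differed in direction between tissues and between its parts. At 39843971, AY036118 and Rn18s-rs5 were at 37.7% against 31.1% in adipose, and at 30.6% against 37.5% in hypothalamus. At 39847391 inside Rn18s-rs5, hypothalamus went from 62.6% to 39% and liver from 62.1% to 41.1%. Such sequence has many copies in the genome, and the copies that these reads came from were not analysed here.

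Homeobox genes stood among the adipose genes with the most called sites (Hlx, Zfhx3, Hoxd3, Irx1), and the hypothesis that called sites favour them was tested. Of 124 homeobox genes chosen by symbol, 41 had a called adipose site, against 49.9 expected for random lists with as many tested sites (range 40 to 60). The percentile of 3.34 (0.565 for genes with higher and 6.855 for genes with lower sites) gave no excess beyond their number of tested sites. The random lists were not matched on methylation level, and these genes were at 14.7% in the control pool. Sites under 20% made up 38.0% of tested and 9.95% of called adipose sites. The test therefore cannot tell whether called sites favour or avoid homeobox genes at equal level.

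Differences at neighbouring sites were alike only over short distances. The correlation of signed deviations between neighbours, over pairs of sites that are not independent, was 0.456, 0.492 and 0.449 at 1 to 50 bp in adipose, hypothalamus and liver, and 0.031, 0.0209 and 0.047 at 200 to 500 bp.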
